A study of Mus musculus with 24 samples.

How the data were processed

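The data were RNA sequencing read counts from 24 mouse pituitary libraries in 8 groups of 3. The groups combine 2 sexes with 4 genotypes: wild type, Cre control (Cre without floxed Egr1), Egr1cKO control (floxed Egr1 without Cre) and Egr1cKO (floxed Egr1 with Cre). Egr1 encodes an immediate early zinc-finger transcription factor, and Egr1cKO is the label for its conditional knockout. The Cre driver and the exon meant to be removed are not given in the sources used here, and counts per gene cannot check the loss of an exon. The labels describe non-stranded polyA libraries made from 1.5 ug of total RNA purified with RNeasy.

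The authors deposited raw counts, whole numbers per Ensembl gene, with no normalization. Per the processing notes of the authors, reads were trimmed with Trim Galore 3.8.2, checked with FastQC and aligned with STAR 2.7.9 to GRCm38. The counting tool and the annotation release behind it are not given in the sources used here. The table holds 35191 genes, of which 35077 identifiers matched GENCODE M21 and 114 did not. Total counts ranged from 15486069 to 26255343 per library. Reads carry no molecular identifiers, so counting intervals and floors cover counting error only. Because the libraries are unstranded, genes with overlapping spans may share reads: Platr9 with Cga, Tshb with Tspan2, Atg9b with Nos3, and Mir186 with Zranb2. How such reads were counted is not known.

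The titles number the libraries in 2 series, 1 for the wild type and Cre control libraries and 1 for the Egr1cKO control and Egr1cKO libraries. Floxed and unfloxed libraries are therefore confounded with these series. Nothing in the labels says that the libraries came from separate animals beyond these numbers, so the p-values measure only the spread between these samples. Xist and Y-linked levels matched the sex label in 24 of 24 libraries. No library duplicated another of its own group: the lowest chi-square per degree of freedom between replicates of 1 group was 16.3 over 24 pairs, among genes with a summed count of at least 20. Pairs across groups were not checked.

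Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings, which left 21927. Libraries were scaled by TMM, and 1 model with a mean for each of the 8 groups left 16 residual degrees of freedom. Each of 14 comparisons was tested with edgeR's robust quasi-likelihood test, and every adjusted p for a gene is a Benjamini-Hochberg value over the 21927 genes at a threshold of 0.05. The comparisons were the Egr1cKO effect (Egr1cKO against Egr1cKO control) and the Cre effect (Cre control against wild type) in each sex, the interaction of sex with each, the Egr1cKO effect beyond the Cre effect in each sex, the female against male difference in each genotype, and Egr1cKO control against wild type in each sex. Fitted log2 fold changes used a prior count of 0.125. Levels are CPM values from edgeR's cpm function on the TMM-scaled library totals, given as mean ± SD with n = 3, and SE is the standard error of the fitted log2 fold change. The median biological coefficient of variation was 0.338.

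The comparisons, the threshold, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Egr1 was to be given in every library. The rule named up to 10 genes in each direction for the Egr1cKO effects and for the sex differences in wild type and Egr1cKO. It named up to 5 in each direction for the other comparisons. These were the genes with the largest log2 fold change among those with an adjusted p under 0.05 and a group mean of at least 1 CPM. Their libraries also had to be without overlap between groups, which chance gives for 10% of genes in 3 against 3, except in the interactions and the effects beyond Cre. Where fewer than 3 genes passed, the 3 with the smallest p were named as not passing. The rule also took the pituitary hormone genes, Gnrhr and up to 4 members of each list with the smallest p. Predicted genes with Gm or Rik names and pseudogenes were skipped. Neb was added in every comparison after its values were seen. For a gene with no count in 1 group, the fold is a bound against 3 counts over the group. With 1 to 3 counts, a ratio with an exact counting interval is given. Lhb, Mc2r, Usp9y and Zfy1 were not analysed here. The text names a part of the list members that the rule took; the called ones were carried through the alternatives. A further 1 is not reported here as a single gene and stays in its list test.

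Lists holding 320 genes in all, numbering 22, were tested in each comparison with fry in limma 3.58.1 on voom values with a prior count of 0.5, which makes 308 tests. The fry p tests whether the genes of a list move one way on balance, was adjusted over the lists of each comparison, and compares no list with other genes. The lists covered gonadotrope, somatotrope and lactotrope, thyrotrope, corticotrope and melanotrope, stem cell and folliculostellate, posterior lobe and neural, endothelial and mural, fibroblast and matrix, leukocyte and macrophage, red blood cell, Y-linked, X inactivation and X escape, EGR family and NAB corepressor, immediate early, estrogen and androgen response, glucocorticoid response, interferon response, circadian clock, cell cycle, cholesterol synthesis, secretory and unfolded protein response genes, and mitochondrially encoded mRNAs. Camera with an estimated correlation was the alternative throughout. Of 48 fry calls 14 held with an estimated correlation: X inactivation and X escape genes in all 4 sex differences, Y-linked genes in all but the Egr1cKO one, gonadotrope genes in wild type and Egr1cKO control, thyrotrope, stem cell and posterior lobe genes in wild type, corticotrope and melanotrope genes in the male Egr1cKO effect, and thyrotrope genes in the female effect beyond Cre.

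Alternatives fixed in advance were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, a model of the compared groups only, a fold threshold of 1.5, and leaving out each library in turn. The mitochondrial share of counts as a covariate, the number of genes detected as a covariate, and a minimum mean of 10 CPM were added after the data had been seen. Genes detected were counted after thinning every library to 15000000 reads. Principal components used log CPM with a prior count of 2. The pipeline was tested on simulated data with 100 genes changed by 2-fold and another 100 by 4-fold. In males 29 of 100 were called at 2-fold and 69 at 4-fold with 0 false calls, and in females 33 and 77 with 3 false calls. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A sample table repeating the column names and groups was not used.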

Results

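Egr1 mRNA was detected in all 24 pituitary libraries, and it was not lower in the libraries labelled Egr1cKO than in their controls. Egr1 (ENSMUSG00000038418, GRCm38 chromosome 18, 34859823 to 34864984) measured 58.3, 238 and 105 CPM in the male Egr1cKO libraries and 51.1, 22.7 and 42.8 CPM in the male Egr1cKO controls. In females the levels were 162, 7.55 and 26.6 CPM in Egr1cKO and 34.2, 11 and 9.79 CPM in the controls. In males the log2 fold change was 1.79 (SE 1.25, edgeR adjusted p = 0.886). In females it was 1.83 (SE 1.26, edgeR adjusted p = 0.468). Neither was called, though all male Egr1cKO levels exceeded the controls. Egr1 also ranged widely in the other groups. It was 19.1, 43.8 and 51.5 CPM in male wild type, 10.9, 167 and 31.8 CPM in female wild type, 486, 74.3 and 25.3 CPM in male Cre control, and 61.7, 486 and 94.8 CPM in female Cre control. Leaving out 1 library moved the Egr1 log2 fold change between 1.07 (without male Egr1cKO replicate 2) and 2.14 (without male Egr1cKO replicate 1) in males. In females it lay between -0.08 (without female Egr1cKO replicate 1) and 2.67 (without female Egr1cKO control replicate 1).

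In males, prolactin mRNA was lower in Egr1cKO than in Egr1cKO control. Prl, the hormone gene of lactotropes (chromosome 13, 27057570 to 27065205), measured 5573 ± 1650 CPM against 33700 ± 16500 CPM (n = 3 each), a log2 fold change of -2.60 with an SE of 0.381 (edgeR adjusted p = 0.00215). Neb, which encodes the giant actin-binding muscle protein nebulin (chromosome 2, 52136647 to 52378474), measured 2.45 ± 0.986 against 18.0 ± 4.8 CPM, and its log2 fold change was -2.87 with an SE of 0.32 (edgeR adjusted p = 3.87e-05). Ryr1, the skeletal muscle calcium release channel (chromosome 7, 29003344 to 29125179), was lower by a log2 fold change of -2.95 (SE 0.516, edgeR adjusted p = 0.0207), at 1.92 against 14.9 CPM. Shc2, a signalling adaptor gene (chromosome 10, 79618051 to 79637918), fell from 9.90 to 1.75 CPM, a log2 fold change of -2.49 (SE 0.333, edgeR adjusted p = 0.000596). These 4 genes belonged to 9 genes called in males, 0 higher and 9 lower, with 1441 genes at an unadjusted p under 0.05. The other 5 were Atg9b (-1.84), Ush1c (-1.81), Kcna2 (-1.39), Ddhd1 (-1.19) and P4ha2 (-0.93), with edgeR adjusted p from 0.0112 for Kcna2 to 0.0419 for P4ha2. DESeq2 called 103 genes in the same comparison.

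Among the other hormone genes of males, Tshb, the thyrotropin subunit gene, had a log2 fold change of 1.40 and missed the threshold (edgeR adjusted p = 0.052). Pomc, the precursor gene of corticotropes and melanotropes, had 1.76 (edgeR adjusted p = 0.481), and growth hormone, Gh, had -1.06 (edgeR adjusted p = 0.608). Fshb (0.20), Cga (0.51) and Gnrhr (0.42) were not called, with edgeR adjusted p of 0.88 for Cga and 1 for Fshb and Gnrhr. The corticotrope and melanotrope list moved up (fry adjusted p = 0.0069) and held in camera (adjusted p = 0.0138). All 13 tested members had positive log2 fold changes with a median of 0.78, none was called among all genes, and 5 were higher when adjusted over the list alone. The posterior lobe list also moved up (fry adjusted p = 0.0477). It had 0 members called of 16, 8 higher adjusted over the list alone, and a camera adjusted p = 0.0923. The somatotrope and lactotrope list moved down (fry adjusted p = 0.0477). It had 0 members higher, 1 lower and 12 not called, 2 lower adjusted over the list alone, and a camera adjusted p = 0.0923. Thyrotrope genes moved up as a list (fry adjusted p = 0.0477). None of its 6 members was called, 3 were higher and 1 lower adjusted over the list alone, and the camera adjusted p = 0.16.

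The male count rested on single libraries. It was 3, 28 and 4 without male Egr1cKO control replicates 1, 2 and 3 in turn, and 3, 2 and 3 without male Egr1cKO replicates 1, 2 and 3. Neb and Shc2 stayed called in 6 of 6 of these fits, and Prl in 5 of 6, its edgeR adjusted p reaching 0.0624 without male Egr1cKO replicate 2. Ryr1, Atg9b, Ush1c, Ddhd1 and P4ha2 lost their call without control replicate 1 or 3 or any 1 Egr1cKO library, and Kcna2 without control replicate 1 or any 1 Egr1cKO library. Their highest edgeR adjusted p came without male Egr1cKO replicate 2 and lay between 0.127 for Kcna2 and 0.475 for P4ha2.

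**Figure D1:**
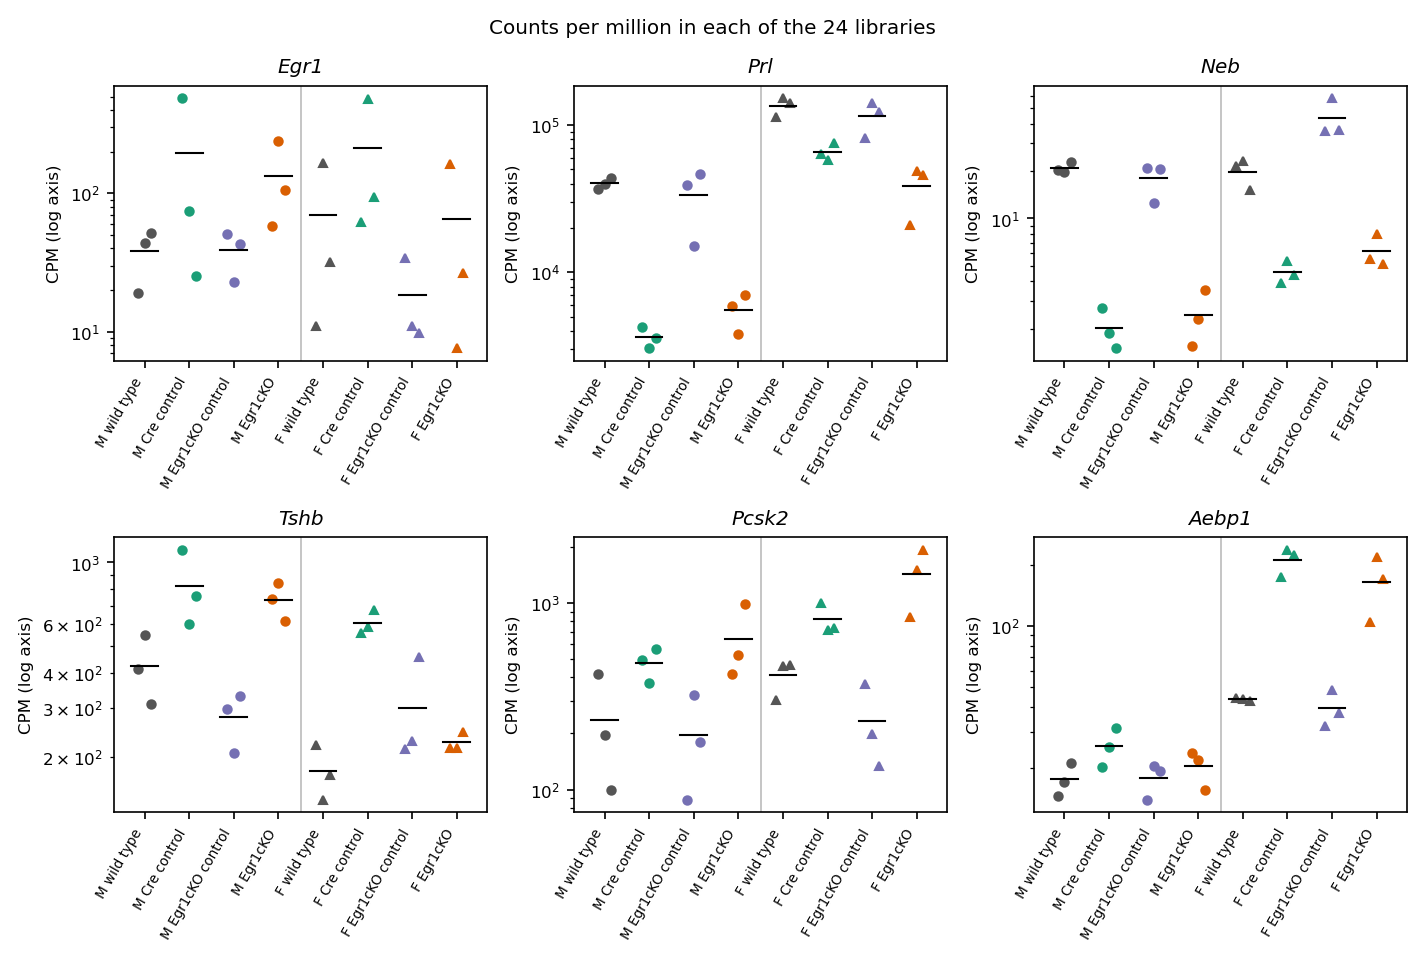
Levels of Egr1, Prl, Neb, Tshb, Pcsk2 and Aebp1 in each of the 24 libraries, in CPM on a log axis, with a bar at each group mean; circles are males and triangles females. Neb lies at or under 8 CPM in the 12 libraries that carry Cre and at or above 12.45 CPM in the others. Egr1 overlaps between Egr1cKO and its control in females, while in males every Egr1cKO library lies above every control.

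In females, the Pomc messenger made up 14.8% ± 5.35 of all counts in Egr1cKO and 2.45% ± 1.37 in Egr1cKO control (SD, n = 3 each). Pomc (chromosome 12, 3954951 to 3960642) rose from 25570 ± 13500 to 165100 ± 74900 CPM, a log2 fold change of 2.69 with an SE of 0.59 (edgeR adjusted p = 0.0169). Pcsk2, the convertase that processes the Pomc product in melanotropes (chromosome 2, 143546156 to 143816285), rose by a log2 fold change of 2.61 (SE 0.525, edgeR adjusted p = 0.0121). Drd2, the dopamine receptor gene expressed in melanotropes and lactotropes, rose by 1.28 (SE 0.296, edgeR adjusted p = 0.0228), and Oxt, the oxytocin gene, by 1.65 (SE 0.332, edgeR adjusted p = 0.00955). Prl fell from 114700 ± 30200 to 38580 ± 15500 CPM, a log2 fold change of -1.57 (SE 0.368, edgeR adjusted p = 0.023). Pou1f1, the transcription factor of somatotropes, lactotropes and thyrotropes (chromosome 16, 65520511 to 65535005), fell from 199 to 56.4 CPM, a log2 fold change of -1.82 (SE 0.302, edgeR adjusted p = 0.00221). The retinoid receptor gene Rxrg (chromosome 1, 167598384 to 167639623) had a log2 fold change of -1.66 (SE 0.227, edgeR adjusted p = 0.00018), and Neb had -2.80 (SE 0.312, edgeR adjusted p = 2.62e-05). Gh (-1.35, edgeR adjusted p = 0.073), Tshb (-0.41, 0.437), Fshb (-0.12, 0.937), Cga (-0.21, 0.816) and Gnrhr (-0.33, 0.846) were not called.

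The female comparison called 484 genes, 167 higher and 317 lower, with 4227 at an unadjusted p under 0.05. The largest increases named by the rule were Dkk2 (4.61), Sh2d2a (3.91), Tph2 (3.72), Gfra4 (3.28), H2-Eb2 (3.21), Cdh13 (3.18), Eva1a (2.82), Pomc, Cda (2.69) and Rnase1 (2.67). The 10 largest decreases had no count in any female Egr1cKO library, which limits them to a bound. Jph2 was at least 89.8-fold lower, Fam243 at least 53.3-fold, Pdha2 at least 52.0-fold, Mir186 at least 47.5-fold and BB123696 at least 46.8-fold lower. Zbbx was at least 39.8-fold lower, Mir1188 at least 35.0-fold, Ltb at least 34.0-fold, Lilra6 at least 33.1-fold and Ankrd34b at least 28.2-fold lower. The female Egr1cKO libraries also held fewer genes at equal depth, 19277 ± 1014 against 22007 ± 2133 in the control, and a larger mitochondrial share of counts, 9.43% ± 0.884 against 4.90% ± 1.76.

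The somatotrope and lactotrope list moved down in females (fry adjusted p = 0.0263). It had 1 member higher, 3 lower and 9 not called, 1 higher and 5 lower adjusted over the list alone, and a camera adjusted p = 0.216 with an estimated correlation. The corticotrope and melanotrope list moved up (fry adjusted p = 0.0313) with 2 members higher and 11 not called, 5 higher and 1 lower adjusted over the list alone, and a camera adjusted p = 0.156 with an estimated correlation. The posterior lobe list moved up (fry adjusted p = 0.0313) with 1 member higher and 15 not called, 3 higher adjusted over the list alone, and a camera adjusted p = 0.156 with an estimated correlation. The leukocyte and macrophage list moved up (fry adjusted p = 0.0313) with 0 of 16 members called, 3 higher adjusted over the list alone, and a camera adjusted p = 0.156 with an estimated correlation. Of the genes called in males, 6 were called in females too, all lower, where independent calls would share 0.13.

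Single libraries mattered in females as well. The count was 142 and 282 without female Egr1cKO control replicates 2 and 3, and 178 without female Egr1cKO replicate 3. Jph2, Zbbx, Ankrd34b and Neb stayed called in 6 of 6 fits. Gfra4 and Eva1a were lost only without control replicate 2, at edgeR adjusted p of 0.0607 and 0.0742. Pou1f1 and Rxrg also stayed called in 6 of 6. Oxt was lost only without control replicate 2 (0.0578), and Drd2 without control replicate 2 or 3 or Egr1cKO replicate 2, up to 0.126. Pomc and Pcsk2 were lost without control replicate 2 or 3 or Egr1cKO replicate 3, up to 0.0818 and 0.0784, and Prl without control replicate 2 or 3 or Egr1cKO replicate 1 or 3, up to 0.101. The other genes named by the rule were each lost in 2 to 6 of the 6 fits, and across them each of the 6 libraries ended a call. Their highest edgeR adjusted p ranged from 0.0699 for BB123696 to 0.21 for Dkk2, both without female Egr1cKO replicate 3. A model of only these groups ended 8 of the 34 named calls it tested: Dkk2, Sh2d2a, Tph2, Cda, Lilra6, Ltb, Mir1188 and Ankrd34b (edgeR adjusted p from 0.0649 for Ltb to 0.17 for Tph2, the highest over their alternatives). Sh2d2a and Cda were also lost with either covariate and Dkk2 with genes detected. With the mitochondrial share as a covariate the Egr1cKO effect in females had 1899 calls, and Pomc was no longer called (edgeR adjusted p = 0.0717, the highest over its alternatives). Its log2 fold change went from 2.69 with an SE of 0.59 to 2.28 with an SE of 0.753, and with genes detected to 2.29 with an SE of 0.68 (edgeR adjusted p = 0.0631), so a smaller change and a larger SE ended the call.

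Few genes were called as responding to Egr1cKO differently in females and males. Aebp1, a collagen-binding matrix protein gene (chromosome 11, 5861947 to 5872088), differed by a log2 of 1.88 (SE 0.337, edgeR adjusted p = 0.0388), with 165 ± 57.2 CPM in female Egr1cKO and 39.2 ± 8.39 in female control. Hepacam2, an immunoglobulin-family adhesion gene (chromosome 6, 3457096 to 3498298), differed by -1.69 (SE 0.308, edgeR adjusted p = 0.0388), with 20.9 ± 0.701 CPM in female Egr1cKO and 79.5 ± 15.1 in female control. Spn, the leukocyte sialophorin gene (chromosome 7, 127132232 to 127137823), had 1 count in female Egr1cKO and 125 in female control (edgeR adjusted p = 0.0388). Aebp1 and Hepacam2 also shifted in female Cre control, which has no floxed Egr1: Aebp1 measured 211 ± 33.1 CPM there and 43.5 ± 0.698 in female wild type, and Hepacam2 31.9 ± 1.92 and 108 ± 40.2. Their Egr1cKO effect in females differed from the Cre effect by a log2 of -0.21 for Aebp1 (edgeR adjusted p = 0.895) and -0.17 for Hepacam2 (0.915). Spn had 101 counts in female Cre control. The interaction of sex and Egr1cKO called 5 genes, 1 higher and 4 lower, with 1851 at an unadjusted p under 0.05. The other called genes were the predicted genes Gm33172 and Gm37233, named after their values were seen. Tshb differed by -1.81 and missed the threshold (edgeR adjusted p = 0.114). The thyrotrope list moved down (fry adjusted p = 0.0436) with 0 of 6 members called, 2 lower adjusted over the list alone, and a camera adjusted p = 0.458 with an estimated correlation. Its median was -0.94 but its mean 0.17, because Sox14, a gene with few counts, went the other way. For the sex by Egr1cKO interaction the count fell to 0 without male control replicate 2 or 3, female control replicate 2 or 3, or male Egr1cKO replicate 1 or 2. It was 3 without female control replicate 1 or female Egr1cKO replicate 3, and 19 without female Egr1cKO replicate 1. Aebp1 stayed called in 2 of 12 fits, without male control replicate 1 or female Egr1cKO replicate 1. Spn stayed in 1, without female Egr1cKO replicate 3, and Hepacam2 in 1, without female Egr1cKO replicate 1. Their highest edgeR adjusted p, 0.182, 0.182 and 0.251, came without male control replicate 2. Each also lost its call with genes detected as covariate, Aebp1 and Spn in a model of only these groups, Aebp1 and Hepacam2 with a minimum mean of 10 CPM, and Spn with the mitochondrial share (edgeR adjusted p up to 0.0873, 0.0919 and 0.129 over the alternatives of Aebp1, Spn and Hepacam2). Aebp1 lay between 1.88 and 1.92 and Hepacam2 between -1.70 and -1.31 over these alternatives, and with genes detected the fitted value of Spn went from -6.67 to -6.88.

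Carrying Cre without floxed Egr1 went with lower prolactin mRNA in males. Prl measured 3630 ± 605 CPM in male Cre control and 40060 ± 3440 in male wild type (n = 3 each), a log2 fold change of -3.46 with an SE of 0.395 (edgeR adjusted p = 3.1e-05). Neb measured 2.03 ± 0.614 against 21 ± 1.74 CPM, a log2 fold change of -3.38 (SE 0.327, edgeR adjusted p = 2.11e-06). Ryr1 (-2.43, edgeR adjusted p = 0.033), the aryl hydrocarbon receptor repressor gene Ahrr (-4.32, 0.0166), and Klk1b27 (-3.06, 0.00993), a kallikrein with close paralogs, were lower. Nell1 (1.90, edgeR adjusted p = 0.0152), the cadherin gene Fat4 (1.41), Fxyd6 (1.31), the beta-arrestin gene Arrb1 (1.30) and Adgra2 (1.15, edgeR adjusted p = 0.0435) were higher. Gh missed the threshold at -1.76 (edgeR adjusted p = 0.0642), and Pomc (0.54), Tshb (0.96), Fshb (0.61), Cga (0.74) and Gnrhr (0.75) were not called. The comparison called 51 genes, 8 higher and 43 lower, with 2378 at an unadjusted p under 0.05. The somatotrope and lactotrope list moved down (fry adjusted p = 0.00735) with 1 member lower and 12 not called, 1 higher and 4 lower adjusted over the list alone, and a camera adjusted p = 0.0803 with an estimated correlation. The corticotrope and melanotrope list moved up (fry adjusted p = 0.00953) with 0 of 13 called, 2 higher adjusted over the list alone, and a camera adjusted p = 0.062 with an estimated correlation. Thyrotrope genes moved up (fry adjusted p = 0.0244) with 1 member lower, Rxrg, and 5 not called, 5 higher and 1 lower adjusted over the list alone, and a camera adjusted p = 0.0803 with an estimated correlation.

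For the Cre effect in males the count was 11, 24 and 16 without male wild type replicates 1, 2 and 3, and 4, 9 and 7 without male Cre control replicates 1, 2 and 3. Prl and Neb stayed called in 6 of 6 of these fits. Fat4, Fxyd6, Arrb1, Adgra2 and Ryr1 stayed called in none, and Nell1, Ahrr and Klk1b27 in 2. The highest edgeR adjusted p ranged from 0.0827 for Nell1, without male wild type replicate 3, to 0.266 for Adgra2, without male Cre control replicate 3. Adgra2 was also lost in a model of only these groups (0.0874, the highest over its alternatives).

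The genes lower in male Egr1cKO were largely those lower in male Cre control. Of 9 genes called in male Egr1cKO, 7 were also called in male Cre control, Prl and Neb among them, and all 7 were lower in both. Independent calls would share 0.0176. All 9 and all 51 called genes had the same sign in the other comparison, as did 68% of all tested genes. Across 11260 genes with a mean log2 CPM of at least 3, the log2 fold changes of both comparisons correlated with r = 0.71 (rho 0.704). Genes are not independent replicates, so no p is attached. In females the overlap was 71 genes, 20 higher and 51 lower, and r was 0.499 (rho 0.452). These comparisons share no libraries.

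**Figure D2:**
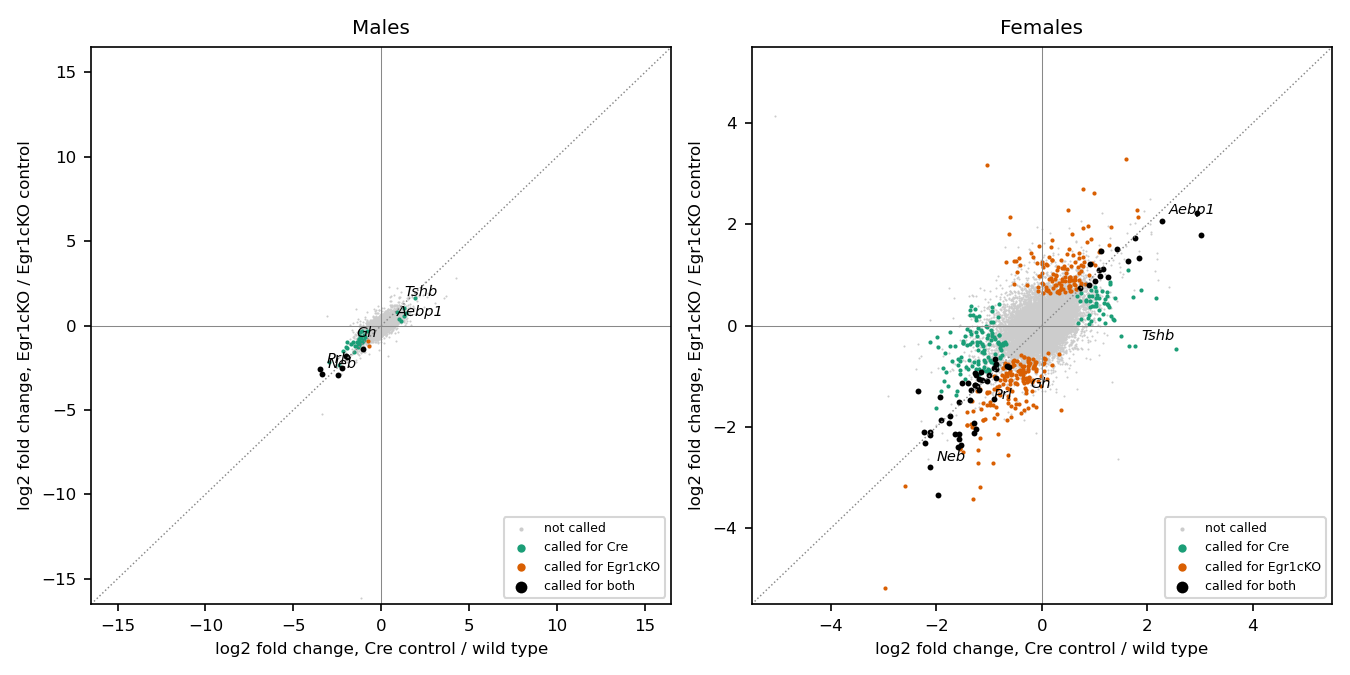
Log2 fold change of Egr1cKO against its control plotted on that of Cre control against wild type, for each sex, over 11260 genes with a mean log2 CPM of at least 3; the dotted line marks equal values. The male panel has r = 0.71 across genes and the female panel r = 0.499, and Neb and Prl lie at negative values on both axes in both panels.

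In females, Tshb was higher in Cre control than in wild type. It (chromosome 3, 102775465 to 102782718) rose from 178 ± 40.7 to 605 ± 61.1 CPM (n = 3 each), a log2 fold change of 1.77 with an SE of 0.278 (edgeR adjusted p = 0.00188). Cga, the common subunit of the glycoprotein hormones (chromosome 4, 34893779 to 34907370), rose by 1.51 (SE 0.362, edgeR adjusted p = 0.0393). The calcium channel gene Cacna1f (chromosome X, 7607083 to 7635196) rose by 3.02 (SE 0.357, edgeR adjusted p = 6.15e-05), from 3.5 to 28.4 CPM. The transcription factor genes Neurod1 (2.16, edgeR adjusted p = 0.00056), Isl1 (1.24, 0.00785) and Foxl2 (1.27, 0.0262) were higher. Neb was lower by -2.11 (SE 0.308, edgeR adjusted p = 0.000957), and Prl missed the threshold at -1.04 (edgeR adjusted p = 0.144). Gh (-0.35), Pomc (0.78), Fshb (1.05) and Gnrhr (-0.56) were not called. The other named increases were Cck (3.39), Ptpn5 (2.93), Trbc2 (2.91) and Il11, with 86 counts against 1 and a ratio of 90.1 (exact counting interval 15.8 to 3600). Mchr1 was lower, with 5 counts against 241, and the genes without a count in female Cre control were Ngp (at least 40.4-fold lower), Cc2d2b (38.5), Gpr139 (37.5) and Mettl11b (20.4). The comparison called 265 genes, 81 higher and 184 lower, with 3680 at an unadjusted p under 0.05.

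Lists moved by fry in female Cre control, and none of these calls held with an estimated correlation. The thyrotrope list moved up (fry adjusted p = 0.00228, camera adjusted p = 0.0815). It had 2 of 6 members higher, 4 not called and 2 higher adjusted over the list alone. The stem cell and folliculostellate list moved up (fry adjusted p = 0.00228, camera adjusted p = 0.0519). It had 2 higher, 19 not called and 4 higher adjusted over the list alone. Its called members were Hes1 (1.20, edgeR adjusted p = 0.00833) and Rbpms (1.08, 0.0107). The gonadotrope list moved up (fry adjusted p = 0.0355, camera adjusted p = 0.163). It had 1 higher, 1 lower and 15 not called, and 1 and 1 adjusted over the list alone. The corticotrope and melanotrope list moved up (fry adjusted p = 0.0355) with 1 higher and 12 not called, 3 higher and 1 lower adjusted over the list alone, and a camera adjusted p = 0.163 with an estimated correlation. The somatotrope and lactotrope list moved down (fry adjusted p = 0.00969) with 1 lower and 12 not called, 1 higher and 5 lower adjusted over the list alone, and a camera adjusted p = 0.0815 with an estimated correlation. The circadian clock list moved down (fry adjusted p = 0.0442) with Dbp lower (-1.74, edgeR adjusted p = 0.0406) and 16 not called, 1 higher and 6 lower adjusted over the list alone, and a camera adjusted p = 0.185 with an estimated correlation.

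For the Cre effect in females, leaving out female wild type replicate 1 raised the count from 265 to 3603. It was 61 and 66 without female wild type replicates 2 and 3, and 90, 104 and 29 without female Cre control replicates 1, 2 and 3. Female wild type replicate 1 had 10.1% mitochondrial counts in a group with 4.96% ± 4.42. Cacna1f, Gpr139, Mchr1, Tshb, Neurod1 and Neb stayed called in 6 of 6 of these fits, while Cga stayed called in 1, its edgeR adjusted p reaching 0.16 without female wild type replicate 2. Cga was also lost with either covariate and in a model of only these groups (up to 0.267 over its alternatives). The other genes named by the rule were lost in 3 to 5 of the 6 fits, and across them each library except female wild type replicate 1 ended a call, with a highest edgeR adjusted p from 0.089 for Cc2d2b, without female Cre control replicate 3, to 0.17 for Cck, without female wild type replicate 2. Among the list members, Isl1 was lost without female wild type replicate 2 (0.0667), Foxl2 without female wild type replicate 2 or female Cre control replicate 2 or 3 (up to 0.147), Hes1 without female wild type replicate 3 or female Cre control replicate 2 (up to 0.0689) and Rbpms without female wild type replicate 2 or 3 or female Cre control replicate 3 (up to 0.0873). Dbp stayed called only without female wild type replicate 1 (up to 0.177 otherwise). The mitochondrial share as a covariate ended 10 of 25 named calls and genes detected 6, Cck and Dbp with each, and Ptpn5, Trbc2 and Ngp with the mitochondrial share. The called somatotrope and lactotrope member and 1 of 2 called gonadotrope members were called with neither. A model of only these groups called 2 genes and ended 23 of the 24 named calls it tested. Cacna1f was kept, and Tshb, Neurod1 and Neb were not called (edgeR adjusted p = 0.142 for each, the highest over their alternatives), although over all alternatives Tshb stayed between 1.67 and 1.77, Neurod1 between 1.99 and 2.16 and Neb between -2.21 and -2.11.

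The Cre effect differed between the sexes for Cacna1f, by a log2 of 3.20 (SE 0.482, edgeR adjusted p = 0.0101), and this call stayed in 12 of 12 leave-one-out fits. Further genes with a higher response in females were Platr9 (2.63, edgeR adjusted p = 0.0259), the vesicular monoamine transporter gene Slc18a2 (2.59, 0.0278), the interferon-induced GTPase gene Iigp1 (2.11, 0.0358) and Psmg4 (2.0, 0.0337). Genes with a lower response in females were Gpr139 (0 counts in female Cre control, edgeR adjusted p = 0.0299), Cdh22 (-4.21, 0.0299), Klf12 (-2.91, 0.0259), Kcnh1 (-2.53, 0.0402) and the semaphorin gene Sema3a (-2.43, 0.0299). The interaction called 28 genes, 14 in each direction, with 3947 at an unadjusted p under 0.05. Prl differed by 2.42 and just missed the threshold (edgeR adjusted p = 0.0503). Across 11260 genes the Cre effects of males and females had r = -0.121. For the sex by Cre interaction the count was 9, 4 and 106 without male wild type replicates 1, 2 and 3, and 4339, 7 and 2 without female wild type replicates 1, 2 and 3. It was 532, 1 and 2 without male Cre control replicates 1, 2 and 3, and 2, 1 and 3 without female Cre control replicates 1, 2 and 3. The calls other than Cacna1f stayed in 3 to 8 of 12 fits and ended in fits without each library except male wild type replicate 3, female wild type replicate 1 and male Cre control replicate 1. Their highest edgeR adjusted p ranged from 0.0816 for Platr9 and Klf12, without male Cre control replicate 2, to 0.178 for Kcnh1, without female wild type replicate 3. A model of only these groups ended 8 of the 10 named calls, all but Cacna1f and Cdh22. The mitochondrial share as a covariate ended 7, all but Cacna1f, Platr9 and Slc18a2, and genes detected ended Kcnh1. With the mitochondrial share the median absolute value of the 10 genes went from 2.61 to 2.64; among the lost calls Kcnh1 moved from -2.53 to -1.76 and Sema3a from -2.43 to -2.53. Over their alternatives the edgeR adjusted p reached 0.0857 for Gpr139 to 0.186 for Kcnh1.

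Subtracting the Cre effect from the Egr1cKO effect left 0 genes in males and 1 in females with edgeR. In males edgeR called 0 genes and DESeq2 0, with 233 at an unadjusted p under 0.05, and the smallest p belonged to Pianp (1.33), Mien1 (1.70) and Bpifb1, which did not pass (edgeR adjusted p = 1 each). In females edgeR called 1 gene, the noncoding Platr9 (chromosome 4, 34906124 to 34911481), at -3.02 (SE 0.442, edgeR adjusted p = 0.0062), with 2151 at an unadjusted p under 0.05. DESeq2 called 92 genes in the same comparison, and edgeR 124 with the mitochondrial share and 12 with genes detected as covariate. The span of Platr9 overlaps that of Cga, which was at -1.71 (edgeR adjusted p = 0.337). Tshb (-2.18, edgeR adjusted p = 0.0683), Spn (edgeR adjusted p = 0.1) and the lipoprotein lipase gene Lpl (1.63, edgeR adjusted p = 0.1) did not pass. In females thyrotrope genes moved down (fry adjusted p = 0.00287) and held in camera (adjusted p = 0.0432 with an estimated correlation), with 0 of 6 members called and 2 lower adjusted over the list alone. In females the count was 3 and 2 without Egr1cKO control replicates 1 and 2, and 24 without Egr1cKO replicate 1. It was 1282 without wild type replicate 1 and 2 without Cre control replicate 3. Platr9 stayed called in 12 of 12 of these fits. It was lost in a model of only these groups (edgeR adjusted p = 0.125, the highest over its alternatives).

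Male and female wild type pituitaries differed in the hormone genes of gonadotropes, lactotropes and thyrotropes. Fshb, the follicle-stimulating hormone subunit (chromosome 2, 107056140 to 107059656), measured 36.2 ± 19.6 CPM in females and 772 ± 128 in males (n = 3 each), a log2 difference of -4.42 (SE 0.581, edgeR adjusted p = 0.00057). Prl was higher in females, 134800 ± 19500 against 40060 ± 3440 CPM, by 1.75 (SE 0.37, edgeR adjusted p = 0.0271). Tshb was lower in females by -1.25 (SE 0.275, edgeR adjusted p = 0.0412). Crhbp, the binding protein of corticotropin-releasing hormone (chromosome 13, 95431371 to 95444924), was higher in females by 8.04 (SE 0.631, edgeR adjusted p = 1.28e-07), with 90.3 against 0.318 CPM. Grem1, an antagonist of bone morphogenetic proteins, was lower by -4.02 (edgeR adjusted p = 0.00593), and the phosphatase gene Ptpn5 was higher by 4.19 (edgeR adjusted p = 0.00814). Xist was higher by 11.07, and Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in wild type females. Further named genes were higher for Csmd3 (at least 63.9-fold), Rnase1, Vwde (2.72), Pcdh11x (2.36), Sema3a (2.36), Ntn1 (2.27) and Chml (1.86), and lower for Drd4 (at least 59.8-fold), Gpr101, Alk (-2.69) and Fyb2 (-2.58). Gh (-1.10), Pomc (0.46), Cga (-1.01) and Gnrhr (-0.45) were not called. The comparison called 62 genes, 26 higher and 36 lower in females.

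In wild type the gonadotrope list moved down in females (fry adjusted p = 0.000438) with 1 of 17 members lower and 16 not called, and 4 lower adjusted over the list alone. The thyrotrope list moved down (fry adjusted p = 0.00934) with 1 of 6 lower and 2 lower adjusted over the list alone, a median of -0.29 and a mean of 0.05. The stem cell and folliculostellate list moved down (fry adjusted p = 0.00962) with 1 of 21 lower and 5 lower adjusted over the list alone. The posterior lobe list moved up (fry adjusted p = 0.00962) with 0 of 16 called and 7 higher adjusted over the list alone. All 4 of these lists held in camera, at adjusted p of 0.00631, 0.0271, 0.0271 and 0.016. The gene count was 25 and 27 without male replicates 1 and 2, and 1024, 25 and 26 without female replicates 1, 2 and 3. Fshb, Crhbp, Rnase1, Vwde, Sema3a, Xist and the 4 Y-linked genes stayed called in 6 of 6 fits. Prl lost its call without any 1 male library or female replicate 2 or 3 (edgeR adjusted p up to 0.166), and Tshb without male replicate 1 or 2 or female replicate 2 or 3 (up to 0.299). Tshb was also lost with DESeq2 size factors. A model of only these groups called 9 genes and ended 20 of the 28 named calls, among them Prl (edgeR adjusted p = 0.671), Tshb (0.589), Rnase1 (0.316), Vwde and Sema3a (0.295 each), the highest over their alternatives. It kept Fshb, Crhbp, Grem1, Xist and the 4 Y-linked genes. Grem1 was lost without female replicate 3 (0.0792), Csmd3 without male replicate 2 (0.0511), and Pcdh11x and Chml without male replicate 1 (0.0681 each). Drd4 was lost without female replicate 2 or 3, Ptpn5 and Alk without male replicate 1 or 2 or female replicate 2, and Ntn1, Gpr101 and Fyb2 without any 1 of these 4 libraries, with edgeR adjusted p up to 0.153 for Ntn1.

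The sex difference of Fshb was present in every genotype, at -3.98 in Cre control (edgeR adjusted p = 0.000588), -3.61 in Egr1cKO control (0.0024) and -3.93 in Egr1cKO (0.00046), and stayed called in all leave-one-out fits. Prl was higher in females by 4.17 in Cre control (edgeR adjusted p = 3.82e-07), 1.77 in Egr1cKO control (0.0231) and 2.79 in Egr1cKO (9.47e-05). It was not called in Egr1cKO control without male replicate 1 or 2 or female replicate 2, up to 0.154. Tshb was lower in females in Egr1cKO by -1.70 (SE 0.278, edgeR adjusted p = 0.000575) and was not called in Cre control (-0.44, 0.332) or Egr1cKO control (0.11, 0.934). In Egr1cKO, Cga was lower in females by -1.39 (edgeR adjusted p = 0.016), the estrogen receptor gene Esr1 by -1.39 (0.00112) and the thyrotrope and gonadotrope transcription factor gene Gata2 by -1.56. The estrogen-regulated gene Greb1 was higher by 2.50 (edgeR adjusted p = 5.24e-06) and the relaxin receptor gene Rxfp1 by 6.85 (0.00185). Greb1, Gata2, Esr1 and Rxfp1 stayed called in 6 of 6 leave-one-out fits, but Esr1 was lost with either covariate (edgeR adjusted p up to 0.297 over its alternatives), its value moving from -1.39 to -0.72 with the mitochondrial share. Other genes named by the rule in Egr1cKO were higher in females for Wdr64, Ptpn5 (8.78), Tmprss11a, Tcp10a, Zfp804a (4.12), Cdh20 (4.10) and Mir99a (4.09), and lower for Gpr101 (at least 176-fold), Slc7a11 (at least 90.3-fold), Cntnap4, Ptx4, Mir186 and Lilra6. Of these, Tcp10a was lost without male Egr1cKO replicate 1 (0.0616), Tmprss11a and Cdh20 without any 1 of the 6 libraries (up to 0.16 and 0.13), and Mir99a without male Egr1cKO replicate 1 or 2 or female Egr1cKO replicate 2 or 3 (up to 0.129). Cga was lost without male Egr1cKO replicate 2 or female Egr1cKO replicate 1 or 2, up to 0.0851, and with either covariate (up to 0.254 over its alternatives), where its value was -1.41 and -1.48 and its SE went from 0.361 to 0.51 and 0.525. Tmprss11a, Tcp10a, Mir99a, Ptx4, Mir186 and Lilra6 were lost with either covariate as well, and Cdh20 with genes detected (edgeR adjusted p from 0.131 for Cdh20 to 0.889 for Mir99a, the highest over their alternatives). The value of Mir99a dropped from 4.09 to 0.98 with the mitochondrial share and 0.63 with genes detected. Crhbp had 1 count in male Egr1cKO against 8692 in female Egr1cKO, a ratio of 9240 (exact counting interval 1660 to 365000). The gonadotrope list moved down in females in Cre control (fry adjusted p = 0.00142; 5 of 17 lower; 1 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.113 with an estimated correlation). It did so in Egr1cKO control (fry adjusted p = 0.000154) with 2 lower, 4 lower adjusted over the list alone, and a camera adjusted p = 0.00857 with an estimated correlation. In Egr1cKO (fry adjusted p = 3.4e-05) it had 1 higher and 5 lower, 1 higher and 8 lower adjusted over the list alone, and a camera adjusted p = 0.125 with an estimated correlation. The thyrotrope list moved down in Egr1cKO (fry adjusted p = 7.96e-05) with 3 of 6 lower, 1 higher and 4 lower adjusted over the list alone, and a camera adjusted p = 0.17 with an estimated correlation. In Egr1cKO 2 of the 6 called gonadotrope members and 1 of the 3 thyrotrope members stayed called with each covariate, and in Cre control 2 of 5 gonadotrope members.

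The number of genes that differed between the sexes was 62 in wild type, 791 in Cre control (350 higher, 441 lower), 99 in Egr1cKO control (41 higher, 58 lower) and 2863 in Egr1cKO (1204 higher, 1659 lower). Wild type and Egr1cKO control shared 30 called genes in the same direction, 11 higher and 19 lower. Egr1cKO control and Egr1cKO shared 77, and Cre control and Egr1cKO 491, with r = 0.85 across 11260 genes. Whether the sex difference changed with Egr1cKO was tested gene by gene as the interaction, which called 5 genes. Female Egr1cKO libraries had the largest mitochondrial share of the 8 groups, 9.43% ± 0.884 against 3.33% ± 0.524 in male Egr1cKO. With this share as a covariate the sex difference in Egr1cKO had 222 calls, that in Cre control 148, that in Egr1cKO control 120 and that in wild type 194. With genes detected as the covariate they had 145, 258, 131 and 153. Of 72 named genes called in Egr1cKO, 21 stayed called with each covariate and 49 were called with neither. In Cre control 28 of 50 stayed called with each, in Egr1cKO control 25 of 26 and in wild type 28 of 28. For the sex difference in Egr1cKO the count was 548 and 759 without male Egr1cKO replicates 1 and 2, and 1863, 1290 and 1492 without female Egr1cKO replicates 1, 2 and 3. In Cre control it was 154 and 237 without male replicates 2 and 3, and 187, 280 and 220 without female replicates 1, 2 and 3. In Egr1cKO control it was 48, 53 and 58 without male replicates 1, 2 and 3. Without female replicates 1, 2 and 3 it was 42, 29 and 232.

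**Figure D3:**
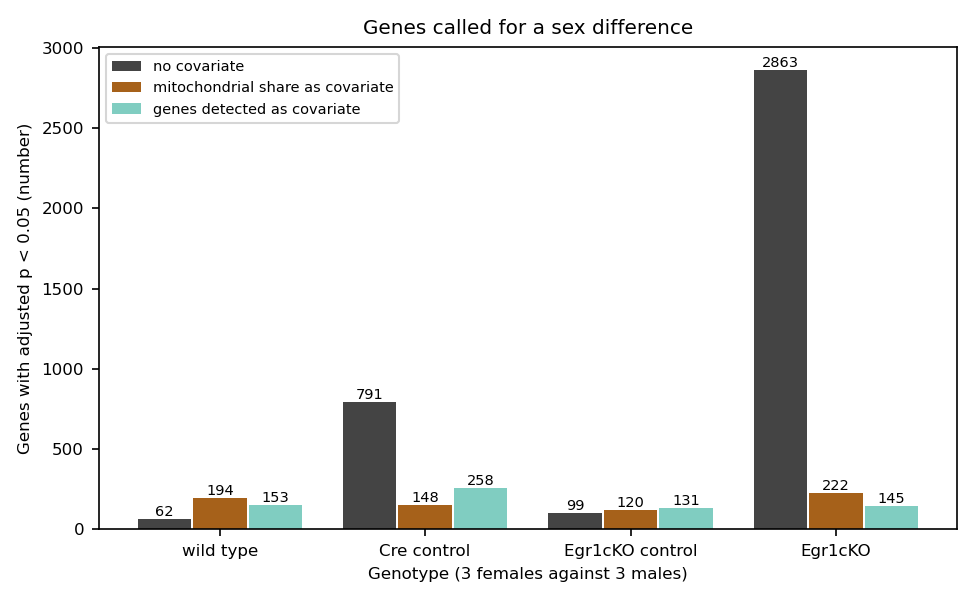
Number of genes called as different between females and males in each genotype (edgeR adjusted p under 0.05), without a covariate, with the mitochondrial share of counts and with the number of genes detected. The Egr1cKO bar falls from 2863 to 222 and 145 with the covariates.

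**Figure D4:**
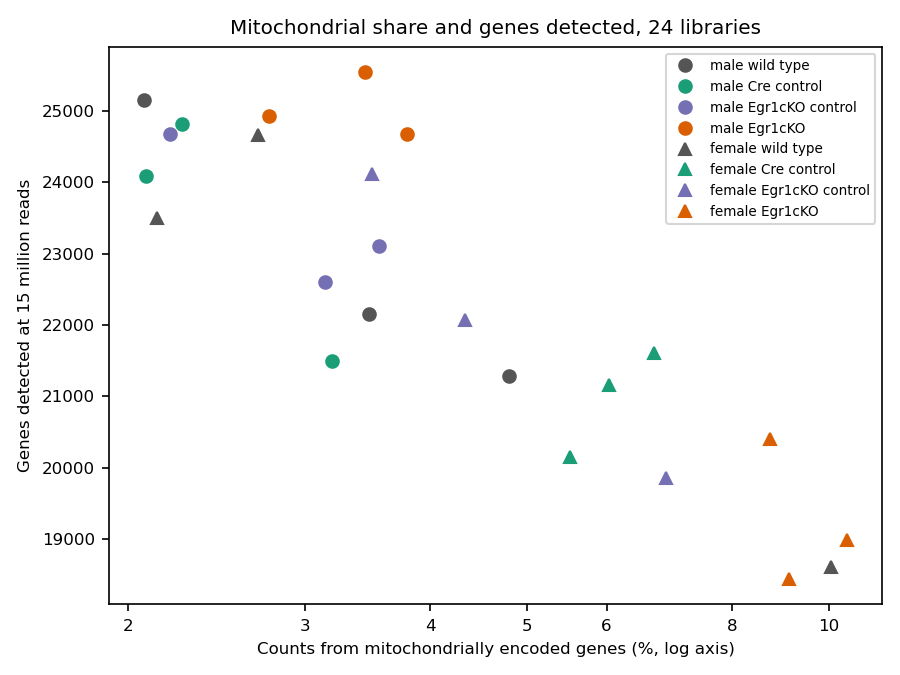
Genes detected at an equal depth of 15000000 reads plotted on the mitochondrial percentage of counts (log axis) for the 24 libraries, by sex and genotype. The relation had r = -0.883, and the 3 female Egr1cKO libraries and female wild type replicate 1 lie at the end with a large mitochondrial share and few genes.

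Egr1cKO control and wild type differ in floxed Egr1 and also in the series of their numbers. In males edgeR called 0 genes and DESeq2 0, with 196 at an unadjusted p under 0.05. The smallest p belonged to the astrocyte and pituicyte gene Gfap (1.77), the retinoic acid hydroxylase gene Cyp26b1 (1.41) and Slco1a4 (1.96), which did not pass (edgeR adjusted p = 1 each). In females edgeR called 0 genes and DESeq2 633, with 3247 at an unadjusted p under 0.05, and edgeR called 312 with the mitochondrial share and 412 with genes detected as covariate. Ints2 (1.02), Eif2s3x (-1.80) and Txlng (1.07) had the smallest p and did not pass (edgeR adjusted p = 0.0701 each). In females the count was 4248 without wild type replicate 1 and 1 without Egr1cKO control replicate 2. The hormone genes were not called in either sex.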

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

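The counts of splits, the test of a few dominant genes and the complexity test of the sex difference were set before their results were seen, and the other tests of explanations were chosen only after the result was seen. The results listed first stand out because the 2 sexes, or Egr1cKO and Cre, differed in a direct test of the difference.

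The Egr1cKO effect differed between the sexes for Aebp1, Spn and Hepacam2, each with an edgeR adjusted p of 0.0388. Aebp1 and Hepacam2 shifted the same way in female Cre control, where Aebp1 measured 211 CPM against 43.5 in wild type and Hepacam2 31.9 against 108, and each of the 3 calls ended under 2 or 3 alternatives (edgeR adjusted p up to 0.129). The thyrotrope list differed between the sexes with a fry adjusted p of 0.0436, which was not kept with an estimated correlation (camera adjusted p = 0.458), and 0 of 6 members were called. The Cre effect differed between the sexes for Cacna1f (edgeR adjusted p = 0.0101), Platr9 and Klf12 (0.0259 each), Slc18a2 (0.0278), Gpr139, Cdh22 and Sema3a (0.0299 each), Psmg4 (0.0337), Iigp1 (0.0358) and Kcnh1 (0.0402). Of these 10 calls, 8 ended in a model of only the compared groups and 7 with the mitochondrial share as a covariate, and only Cacna1f was kept in each alternative run (edgeR adjusted p up to 0.186 for the others). In females, the Egr1cKO effect differed from the Cre effect for Platr9 (edgeR adjusted p = 0.0062) and for the thyrotrope list (fry adjusted p = 0.00287; camera adjusted p = 0.0432 with an estimated correlation). Tshb, a thyrotrope gene, was higher in female Cre control than in wild type and not called in female Egr1cKO against its control.

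The first pattern is that Egr1 was not lower in the libraries labelled Egr1cKO. Egr1 moved with 10 other immediate early genes (Fos, Fosb, Fosl2, Jun, Junb, Jund, Nr4a1, Nr4a2, Nr4a3 and Ier2): the deviations from group means had r = 0.866 and rho = 0.862 over 24 libraries, each with a permutation p of 1e-05, the smallest that the permutations can give and 1e-05 after Benjamini-Hochberg adjustment over 3 relations. The value was 0.824 without the 2 libraries farthest from the median, male Cre control replicate 1 and female Cre control replicate 2, and 0.947 and 0.719 within the wild type and floxed series of 12, so induction at tissue collection may set much of the Egr1 level. A loss hidden by such induction cannot be told apart from no loss, since Egr1 less the mean of the 10 genes differed between Egr1cKO and control by a log2 of 0.148 (0.235 in males and 0.0604 in females, exact two-sided permutation p = 0.795 over 400 regroupings), and the 95% interval from -1.12 to 1.41 includes a halving. A swap of Cre-positive and Cre-negative floxed libraries is argued against by Neb, which was chosen as a marker after its values were seen. A swap needs a partner out of place in the other group, but 0 of 6 Egr1cKO controls lay under the midpoint of 7.92 CPM taken from the wild type series, and the lowest lay above it by a log2 of 0.664 with an SD of 0.291 within groups. Of the Egr1cKO libraries 1 lay just above that midpoint, female replicate 2 at 8 CPM, where the female controls had 35.8 to 57.7 CPM. Earlier versions of this test, replaced after their results had been seen, counted 1 of 12 floxed libraries on the wrong side of this midpoint and 0 with the midpoint of all libraries.

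The second pattern is that the genes lower in male Egr1cKO were also lower in male Cre control. A larger share of intermediate or posterior lobe would lower Prl together with the genes of the other anterior cell types. Some values go with that: Gh was at -1.06 in Egr1cKO and -1.76 in Cre control, Pomc at 1.76 and 0.54, and the corticotrope and melanotrope list moved up in each (fry adjusted p = 0.0069 and 0.00953), as did the posterior lobe list in Egr1cKO (0.0477). As the whole cause it is argued against, because the median log2 fold change of Gh, Cga, Fshb and Tshb lay above that of Prl by 2.95 in Egr1cKO and 4.14 in Cre control, and Gh, the nearest of them, by 1.54 (SE 0.555) and 1.7 (SE 0.571). A first version of this test without Gh, replaced after its result had been seen, gave 3.1 and 4.2. A larger share as part of the change stays open. A difference in library complexity is argued against as well, since with the mitochondrial share as a covariate 7 of 7 shared calls remained. Without the counts of Gh, Prl and Pomc 6 of the 6 shared calls other than Prl remained. TMM scaling already limits the weight of such genes, so this cannot decide whether a few genes taking most of the counts played a part. An effect of carrying Cre, with or without floxed Egr1, could account for the male calls. Of these, 9 of 9 had the same direction in Cre control, against 68% of all tested genes, and 7 were also called there. Whether that effect comes from the Cre protein, the insertion site or the strain was not tested, and a change confined to lactotropes stays open.

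The third pattern is the larger number of sex differences in Egr1cKO, 2863 genes against 62 to 791 in the other genotypes. Omitting 1 library gave 548 to 2794 genes in Egr1cKO and 154 to 974 in Cre control. In Egr1cKO control it gave 29 to 232 and in wild type 25 to 1024. The pattern thus depends on single libraries. Its size depends on the model: with only the compared groups in the fit the counts were 3699 in Egr1cKO, 3066 in Cre control, 1038 in Egr1cKO control and 9 in wild type. A difference in library complexity goes with it. Across the called genes the slope on the mitochondrial share within the 6 other groups had r = 0.617 with the sex difference. These genes are not independent. The slope predicted the direction of 2552, and without female wild type replicate 1 the values were 0.519 and 2084. The sex difference had a regression coefficient of 1.83 on the shift this slope predicts (1.74 without that library). The slope thus predicts less than the full difference. With the mitochondrial share as a covariate the median absolute log2 difference of these genes dropped from 1.06 to 0.506 while the SE moved from 0.273 to 0.283, and with genes detected as covariate to 0.499 with an SE of 0.331, so the calls ended because the differences shrank. A sex difference that depends on Egr1cKO cannot be told apart from it, because the covariates separate the same libraries: 145 calls were left with genes detected as covariate, 1.11 times the count in Egr1cKO control, and 1.85 times with the mitochondrial share. The median absolute Egr1cKO effect in females stayed at 1.33 with the mitochondrial share as a covariate.

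Other splits of the same libraries were counted for every comparison, the real split included. For 10 comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. The Egr1cKO effect in males called 9 genes and the highest other split 0; in females it called 484 and the highest other 1. The Cre effect in males called 51 and the highest other split 45. The sex difference called 791 in Cre control, 99 in Egr1cKO control and 2863 in Egr1cKO, and the highest other splits 1, 0 and 1. In each of these 6 comparisons 1 of 10 splits, the real one, reached the count. For the Cre effect in females 4 of 10 splits reached 265 and the highest other called 1602. For the sex difference in wild type 3 of 10 reached 62 and the highest other called 2445. For Egr1cKO control against wild type the real count was 0, which any split reaches, 10 of 10 in each sex, with a highest other of 0 in males and 4244 in females. These large splits point to a structure of the samples: every split with several times the real count sets female wild type replicate 1 against the other female wild type libraries, such as female Cre control replicates 1 and 2 with female wild type replicate 1 (1602 genes), or female Egr1cKO control replicates 1 and 2 with it (4244 genes).

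The interactions and the effects beyond Cre were regrouped at random, leaving out regroupings that exchange 1 pair of groups whole. With 100 splits, 4 reached the 5 genes of the sex by Egr1cKO interaction (highest other 12), and 3 reached the 28 genes of the sex by Cre interaction (highest other 1808). A first draw had 25 splits, of which 2 reached the count for each (highest other 6 and 2798), and the larger draw was made after those counts had been seen. The share was under 0.05 in the larger draw and not in the first, so chance is not firmly excluded for either interaction. The 1 gene beyond Cre in females was reached by 32 of 100 splits (highest other 1542; first draw 9 of 25, highest other 292), so chance cannot be excluded there. In males the real count was 0, which any split reaches, 100 of 100 and 25 of 25 in the first draw, so these splits decide nothing (highest other 158 and 1).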

How the results depend on the processing

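The covariates and the minimum of 10 CPM are tests that were chosen only after the results had been seen. The cause of a change was not tested except where a value shows it. DESeq2 size factors within edgeR and a fold threshold of 1.5 left all 14 counts within 1.5 times. The Egr1cKO effect beyond Cre and Egr1cKO control against wild type, both in males, stayed at 0 genes in every alternative but the fit without a filter.

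DESeq2 called 103 genes for the Egr1cKO effect in males and 1453 in females, 81 for the sex by Egr1cKO interaction, 264 for the Cre effect in males and 1011 in females, 909 for the sex by Cre interaction, 92 beyond Cre in females, 202 for the sex difference in wild type, 2098 in Cre control and 506 in Egr1cKO control, and 633 for Egr1cKO control against wild type in females.

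Without the filter on low counts the counts, in the same order, were 339, 1142, 167, 704, 1149, 1427, 14 beyond Cre in males and 164 in females, 370, 2426 and 782, then 23 for Egr1cKO control against wild type in males and 805 in females. The Egr1 level in males and the Egr1 level in females then passed the threshold, with log2 fold changes of 1.78 in males (edgeR adjusted p = 2.06e-12) and 1.82 in females (3.16e-13). The cause was measured: the prior degrees of freedom, 0.263 for Egr1 with the filter, became infinite without it. The spread of Egr1 between its own replicates then no longer counted. Over all genes the median prior degrees of freedom also went from 10.3 to infinite. How much of the larger counts of this fit came from that was not tested.

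A model of only the compared groups, which has fewer residual degrees of freedom, called 192 genes for the Egr1cKO effect in males, 8 for the sex by Egr1cKO interaction, 112 for the Cre effect in males and 2 in females, 4 for the sex by Cre interaction, 0 beyond Cre in females, 9 for the sex difference in wild type, 3066 in Cre control and 1038 in Egr1cKO control.

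With the mitochondrial share as a covariate the counts were 193 for the Egr1cKO effect in males and 1899 in females, 109 for the Cre effect in males, 5 for the sex by Cre interaction, 124 beyond Cre in females, 194, 148 and 222 for the sex difference in wild type, Cre control and Egr1cKO, and 312 for Egr1cKO control against wild type in females. With genes detected as covariate they were 941 for the Egr1cKO effect in females, 1 for the sex by Egr1cKO interaction, 161 for the Cre effect in males, 70 for the sex by Cre interaction, 12 beyond Cre in females, 153, 258 and 145 for those sex differences, and 412 for Egr1cKO control against wild type in females. With a minimum mean of 10 CPM, which tests fewer genes, the sex by Egr1cKO interaction had 0 calls, the sex by Cre interaction 188, and Egr1cKO control against wild type in females 29. Camera with an estimated correlation kept 14 of 48 list calls.

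Leaving out 1 library gave counts from 2 to 28 for the Egr1cKO effect in males and 142 to 581 in females, 0 to 19 for the sex by Egr1cKO interaction, 4 to 24 for the Cre effect in males, 29 to 3603 in females, 1 to 4339 for the sex by Cre interaction, 1 to 1282 beyond Cre in females, 25 to 1024, 154 to 974, 29 to 232 and 548 to 2794 for the sex difference in wild type, Cre control, Egr1cKO control and Egr1cKO, and 0 to 4248 for Egr1cKO control against wild type in females. Egr1 lay between 1.07 and 2.14 in males and between -0.081 and 2.67 in females, where it reversed without female Egr1cKO replicate 1 (-0.081). No paired analysis was possible because the labels give no replicate number shared between groups.

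Among single genes that were named and called, 269 calls were kept and 2 lost with DESeq2, 268 and 3 with its size factors, 270 and 1 without the filter, 197 and 69 in the model of the compared groups, 175 and 95 with the mitochondrial share, 187 and 81 with genes detected, 196 and 2 with the minimum of 10 CPM, and 1037 and 673 over the fits that left out 1 library. The sex difference in Egr1cKO reversed with the mitochondrial share as a covariate for mt-Nd4 (-0.00173), and with genes detected for mt-Nd4 (-0.17), mt-Co1 (-0.12) and mt-Cytb (-0.090). None of these 4 values was called. The covariate is itself made of mitochondrial counts for the mt genes. At this depth 29 and 33 of 100 simulated 2-fold changes were called in males and females. A gene that was not called can still differ by 2-fold or more.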

Other observations

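The lists were fixed in advance and the test of the region next to Neb was set before its result was seen, while the tests of the relation between genes detected and the mitochondrial share were chosen only after the result was seen. The cholesterol synthesis list moved down in females in Egr1cKO, Cre control and Egr1cKO control by fry, and none of these calls held with an estimated correlation. In Egr1cKO it moved down (fry adjusted p = 0.000777) with 7 of 18 members lower, among them the enzyme gene Sqle and the sterol carrier gene Stard4 (-1.41), 9 lower adjusted over the list alone, and a camera adjusted p = 0.215 with an estimated correlation. Stard4 and Sqle stayed called in 6 of 6 leave-one-out fits and were lost with either covariate (edgeR adjusted p up to 0.14 and 0.191 over their alternatives). In Cre control (fry adjusted p = 0.0239, camera adjusted p = 0.296) none was called and 4 were lower adjusted over the list alone. In Egr1cKO control (fry adjusted p = 0.0101, camera adjusted p = 0.0971) none was called and 8 were lower adjusted over the list alone. Circadian clock genes were lower in females in Cre control (fry adjusted p = 0.00347; 4 of 17 lower; 1 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.113 with an estimated correlation). They were lower in Egr1cKO as well (fry adjusted p = 0.0273) with 3 lower, 3 lower adjusted over the list alone, and a camera adjusted p = 0.675 with an estimated correlation. In Cre control 0 of the 4 called clock genes stayed called with the mitochondrial share and 1 with genes detected, and in Egr1cKO 0 of 3 with either. Secretory and unfolded protein response genes were lower in Egr1cKO control females (fry adjusted p = 0.0186), with negative values for 20 of 20 members, 0 called, 9 lower adjusted over the list alone, and a camera adjusted p = 0.125 with an estimated correlation. In female Egr1cKO against control this list did not move one way (fry adjusted p = 0.109), yet Sdf2l1 (1.20, edgeR adjusted p = 0.00341), Pdia4 (0.80, 0.0108), Calr (0.97, 0.0154) and Chga (1.10, 0.0174) rose. Sdf2l1 stayed called in 6 of 6 leave-one-out fits, Pdia4 and Calr were lost without female Egr1cKO control replicate 2 or female Egr1cKO replicate 3 (up to 0.0675 and 0.107), and Chga also without female Egr1cKO control replicate 3 (up to 0.0876).

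Mitochondrially encoded mRNAs were higher in females than in males in Egr1cKO (fry adjusted p = 0.0152), with 7 of 12 members higher, mt-Nd2 by 2.01, 10 higher adjusted over the list alone, and a camera adjusted p = 0.215 with an estimated correlation. mt-Nd2 was lost without male Egr1cKO replicate 1 or 2 or female Egr1cKO replicate 3 (edgeR adjusted p up to 0.0919). In Cre control they were higher too (fry adjusted p = 0.0239) with 2 of 12 higher, 9 higher adjusted over the list alone, and a camera adjusted p = 0.234 with an estimated correlation. Posterior lobe genes were higher in females in Cre control (fry adjusted p = 0.0131; 1 of 16 higher; 2 higher adjusted over the list alone; camera adjusted p = 0.113 with an estimated correlation), and the called member was lost with either covariate. In Egr1cKO, females had lower endothelial and mural genes (fry adjusted p = 0.0273) with 3 of 14 lower, 1 higher and 3 lower adjusted over the list alone, and a camera adjusted p = 0.675 with an estimated correlation. These 3, Emcn, Plvap and Kdr, lost their call with either covariate (edgeR adjusted p up to 0.279, 0.528 and 0.629 over their alternatives), and Kdr moved from -1.27 (SE 0.313) to -0.49 (SE 0.323) with the mitochondrial share. Somatotrope and lactotrope genes there moved down (fry adjusted p = 0.04) with 2 higher and 5 lower of 13, 2 higher and 6 lower adjusted over the list alone, and a camera adjusted p = 0.675 with an estimated correlation. Of these 7 called members 5 were called with neither covariate, as were 2 of the 3 stem cell members, 3 of the 5 X inactivation and X escape members and 7 of 7 cholesterol synthesis and mitochondrially encoded members in Egr1cKO. Stem cell and folliculostellate genes were lower in females in Egr1cKO (fry adjusted p = 0.00701; 3 of 21 lower; 3 lower adjusted over the list alone; camera adjusted p = 0.675 with an estimated correlation). They were lower in Egr1cKO control (fry adjusted p = 0.0186) with 2 lower, 2 lower adjusted over the list alone, and a camera adjusted p = 0.217 with an estimated correlation. Y-linked genes were lower in females in all 4 genotypes (fry adjusted p = 2.42e-06 in wild type, 5.23e-06 in Cre control, 2.05e-06 in Egr1cKO control and 3.48e-06 in Egr1cKO), with 4 of 4 members lower and 4 lower adjusted over the list alone. In Egr1cKO the camera adjusted p was 0.0609. X inactivation and X escape genes were higher in females in all 4 (fry adjusted p = 7.03e-09, 4.03e-08, 1.83e-08 and 8.51e-08), with 4, 5, 3 and 5 of 11 members higher and 6, 6, 3 and 5 higher adjusted over the list alone.

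The other 8 lists were called in no comparison. Their lowest fry adjusted p was 0.329 for EGR family and NAB corepressor genes, 0.299 for cell cycle genes, 0.329 for estrogen and androgen response genes, 0.129 for fibroblast and matrix genes, 0.156 for glucocorticoid response genes, 0.199 for immediate early genes, 0.35 for interferon response genes and 0.167 for red blood cell genes.

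The first principal component held 22.2% of the variance and the next 9.64%, and the first had r = 0.95 with the log2 mitochondrial share and r = -0.945 with genes detected. Genes detected fell with the log2 mitochondrial share over 24 libraries (r = -0.883, rho = -0.821, permutation p = 1e-05 for each, the smallest possible, and 1e-05 after Benjamini-Hochberg adjustment over 3 relations). Without female Egr1cKO replicate 3 and female wild type replicate 1, the libraries farthest from the median, r was -0.842, and within the wild type and floxed series of 12 it was -0.909 and -0.91. As deviations from group means r was -0.875 and rho -0.806.

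Neb was at or under 8 CPM in all 12 Cre-carrying libraries. A change in the region next to Neb, as from a transgene or passenger segment, was tested. The median absolute log2 fold change of 13 tested genes within 2 Mb was 0.123, against a median of 0.177 and a 95th percentile of 0.283 over 1954 random windows, which argues against a change shared by the region. A change of single genes there stays open, since 1 of the 13, Rprm, named after its values were seen, was called in a Cre comparison, against 4.09% of tested genes of such level; in females it was lower in Egr1cKO than in its control (-1.45, edgeR adjusted p = 0.00138) and in Cre control than in wild type (-0.91, 0.0454).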
